A study of Arabidopsis thaliana with 8 samples.

How the data were processed

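The series holds 8 Arabidopsis thaliana samples. Processed files of 4 were used: RNA-seq of wild type (Col) and of the hlp1 mutant, and CLIP-seq of CFP-HLP1 and of CFP-HLP1 without its RRM, 1 library each. Per the labels' protocols, CLIP seedlings were 12 days old, grown in long days, and irradiated 2 times at 400 mJ per square centimetre. The 4 poly(A) site samples, 2 per genotype, were not analysed here. Groups came from the sample titles. The gene locus disrupted in hlp1 is not given in the labels, so it was not used as a known target.

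The files deposited by the authors are coverage tracks: for each run of bases on the 5 nuclear chromosomes, a whole-number depth whose sign gives the strand, not scaled to library size. Per the submitters' processing notes, Bowtie 0.12.7 and TopHat 1.3.0 and the build TAIR10 were used. Filters, the treatment of duplicates and of reads with several positions, and the role of each tool are not given in the sources used here. Multiply placed tags could therefore add to depth in repeats, and duplicates could widen true error beyond the counting intervals.

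Reads were recovered as depth summed over a region divided by read length. Most isolated RNA-seq islands were 80 nt long (71.9% and 72.9% in the 2 libraries), so 80 nt was used. Isolated CLIP islands had 14 nt as their shortest length, and the mean tag lengths used were 20.7 and 20.5 nt. Distinct tags were positions where depth rises in the direction of the strand, which counts tags with the same start once. Of HLP1 tags, 82.0% have a start that can be seen in this way, because a tag that ends where another starts hides it. Depth in reads or tags was 12496406 (wild type), 17278368 (hlp1), 2446631 (HLP1) and 61653 (RRM deletion).

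Gene names and spans came from a RefSeq table of the assembly TAIR10.1, used for names and for placing signal in genes; none of its coordinates is printed. A shift test on 20 chromosome pieces, up to 1000 nt each way, placed the spans best at 0 nt in all 20. The table gives no strand, exons, UTRs or sequence. Strand was inferred for 19163 of 27444 nuclear protein-coding genes, those with at least 10 pooled reads and at least 90% of RNA-seq coverage on 1 strand; 6919 had fewer reads and 1362 had mixed strands. The strand matched the letter in a clone-based synonym in 272 of 280 genes. In 5845 of the genes the span overlaps another gene.

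Ratios of hlp1 to wild type used sense reads over gene spans, introns included, scaled by the total over these genes, with exact conditional binomial (Clopper-Pearson) 95% intervals. A gene was counted when its interval lay wholly beyond 2-fold and 1 library had at least 50 reads. Medians of 15 gene lists used members with at least 20 reads and a pseudocount of 1, and were placed among 10000 random lists matched in 20 expression bins. No p-value was computed, since each group is 1 library. CLIP enrichment was distinct sense tags over wild-type reads, scaled to the median gene, with at least 10 tags and an interval wholly above 2. The gene-end ratio used the last 150 nt of non-overlapping genes of at least 600 nt. The planned test on annotated 3' UTRs was replaced by the terminal 400 nt of the span, with at least 20 reads in each library and no other gene in the window. The lists cover flowering time, autonomous pathway and methyltransferases, cleavage and polyadenylation, hnRNP A/B-like, other RNA-binding and SR proteins, the clock, photosynthesis, cold and abscisic acid, salicylate, jasmonate, heat shock, root, floral and seed markers and reference genes.

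The lists and the rule for the genes named were fixed before the data were examined. The rule took for RNA up to 15 in each direction with the interval bound farthest from no change; for CLIP, the 15 highest lower bounds and the 10 with the most tags; for gene ends, up to 5 in each direction; in each list, 2 to 4 members with the largest ratio whose interval excludes no change; and FLC, FCA, FT, SOC1 and the hnRNP A/B-like family. Some genes without known function were left out. Further genes, such as HSP70, HSP101 and the enriched list members, were chosen after their values were seen.

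Alternatives were other scalings (trimmed mean of M-values and median of ratios, written for this purpose), identical positions counted once, all tags, both strands, other minimums, windows and backgrounds, and leaving out overlapping genes. Region shares by UTR, coding sequence and intron, sequence motifs at tags, and isoform choices need an annotation or genome and were not run. The calculations were tested on simulated libraries. Of genes changed 3-fold, 98% of those raised and 90% of those lowered were recovered among 19163 genes, with 0 unchanged genes called. All CLIP enrichments of 5-fold were recovered (100%). The simulated counts varied by Poisson error only, and simulated CLIP tags were proportional to RNA reads. Measured HLP1 tags followed reads only weakly (Spearman rho 0.233). These figures therefore cover counting error, not variation between plants or libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.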

Results

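HLP1 is an Arabidopsis protein related to the hnRNP A/B RNA-binding proteins, and the series asks how it affects polyadenylation and flowering. Coverage tracks of 4 libraries were used. RNA-seq was available for 1 wild-type (Col) and 1 hlp1 mutant library. CLIP-seq, which sequences the RNA fragments crosslinked to a protein by ultraviolet light, was available for 1 library of seedlings carrying CFP-tagged HLP1 and 1 library carrying the same protein without its RNA recognition motif (RRM). The CLIP seedlings were 12 days old. The wild-type and hlp1 RNA-seq tracks held 12496406 and 17278368 reads. The HLP1 CLIP track held 2446631 tags at 1577434 distinct starts, and the track of the RRM deletion held 61653 tags at 58448 distinct starts. The poly(A) site samples, 2 wild-type and 2 mutant, were not analysed here. With 1 library per group, no difference below has a replicate check. The 95% intervals are exact binomial (Clopper-Pearson) intervals unless stated, cover counting error only, and compare these libraries rather than the genotypes.

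The labels do not give the locus of HLP1, so the 10 members of the hnRNP A/B-like family were measured first. AT5G40490 was the member that differed most, with 513 reads in wild type and 147 in hlp1, 4.82-fold lower in hlp1 (0.207 of wild type, interval 0.171 to 0.25). The loss was uneven along the gene. The 5' part of its span, up to the midpoint, had 353 reads in wild type and 146 in hlp1, a ratio of 0.299 (0.245 to 0.364). The 3' part had 160 reads in wild type and 1 in hlp1, a ratio of 0.00452 (0.000114 to 0.0256). AT3G13224 was 2.03-fold higher in hlp1 (1.81 to 2.28, 388 against 1088 reads), AT3G07810 1.65-fold higher (1.42 to 1.94) and AT2G33410 1.34-fold higher (1.21 to 1.47). AT4G14300 was at 0.881 of wild type (0.783 to 0.991). The intervals of AT1G17640, AT4G26650, AT5G47620, AT5G55550 and AT1G58470 included no change, with ratios from 0.880 to 1.32. AT4G26650 had the most reads of the family, 1092 in wild type and 1562 in hlp1. The spans of AT1G17640 and AT4G14300 overlap another gene.

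**Figure D1:**
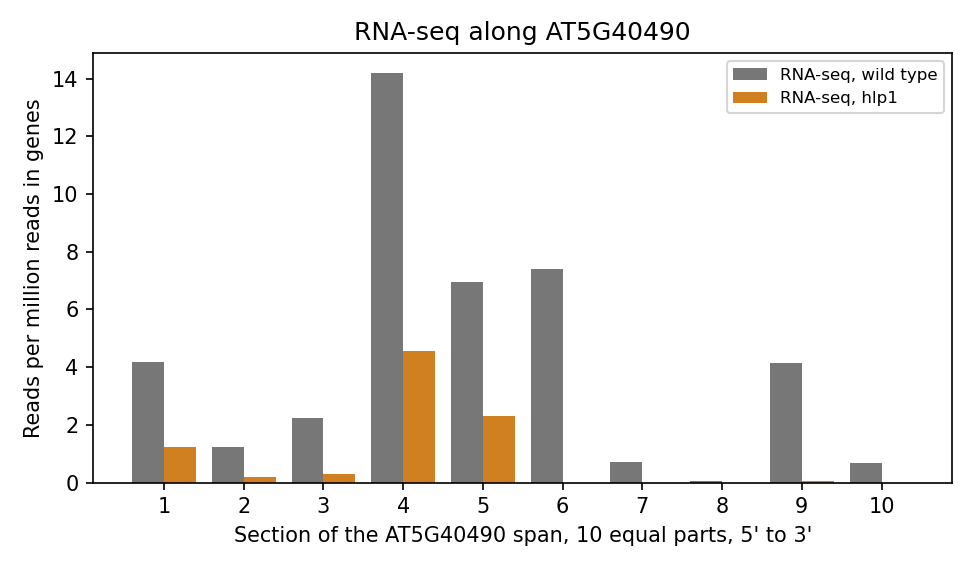
RNA-seq reads along AT5G40490, in 10 equal sections of the gene span from 5' to 3' (x axis), as reads scaled to the library total in protein-coding genes (y axis), for the wild-type and hlp1 libraries (1 each). The hlp1 bars are lower in sections 1 to 5 and nearly absent in sections 6 to 10, where 160 reads were seen in wild type and 1 in hlp1.

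The 2 RNA-seq libraries were then compared over 19163 protein-coding genes, of which 16096 had at least 50 reads in 1 library. FLC, the MADS-box repressor of flowering, was among the few genes clearly higher in hlp1, with 33 reads in wild type and 151 in hlp1, a 3.31-fold difference (2.26 to 4.98). In all, 6 genes were higher and 26 lower in hlp1 with an interval wholly beyond 2-fold. The other higher genes were NAS4, a nicotianamine synthase of metal transport, at 3.69-fold (2.24 to 6.40), XTH4, a xyloglucan endotransglucosylase of the cell wall, at 2.27-fold (2.18 to 2.36), AT3G05980 at 3.51-fold (2.15 to 6.0), and a pair of genes almost silent in wild type. AT1G64795 had 1 read in wild type and 249 in hlp1, a ratio of 180 (32 to 7145), and AT1G75945 had 1 and 165, a ratio of 119 (21.1 to 4744). AT2G06845 went the opposite way, with 317 reads in wild type and 1 in hlp1. With identical read positions counted once, NAS4, AT1G75945 and AT1G64795 remained beyond 2-fold, and FLC, AT3G05980 and XTH4 did not, with ratios of 2.55 (1.73 to 3.83), 3.37 (1.98 to 6.01) and 1.03 (0.913 to 1.16). XTH4 had 3352 and 10516 reads on 500 and 595 positions. Such a count can saturate and does not test the ratio of this gene. The spans of FLC, AT1G64795 and AT2G06845, like that of AT2G30766 below, overlap another gene, so their reads are less certain.

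Lower genes included several of stress and jasmonate pathways. The small heat shock proteins HSP17.4, HSP17.6A, HSP17.6II and HSP17.6C stood at 0.189 (0.104 to 0.327), 0.215 (0.122 to 0.363), 0.25 (0.157 to 0.389) and 0.273 (0.161 to 0.447) of wild type. The 13-lipoxygenases of jasmonate synthesis LOX3 and LOX4 stood at 0.377 (0.326 to 0.434) and 0.331 (0.243 to 0.447), and the jasmonate repressor gene JAZ7 at 0.291 (0.199 to 0.418). The aquaporin gene PIP1;5 fell from 1148 reads to 495, a ratio of 0.312 (0.280 to 0.347), and the transcription factor gene MYB47 had a ratio of 0.391 (0.349 to 0.436). AT5G11330 had 739 and 192 reads, a ratio of 0.188 (0.160 to 0.221). AT1G13609, AT5G35940 and AT2G30766 had ratios of 0.196, 0.257 and 0.358. With identical positions counted once, 7 of the 26 lower genes remained beyond 2-fold, AT5G40490, AT2G06845, AT5G11330, AT1G13609, AT5G35940, HSP17.4 and HSP17.6II; LOX3, LOX4, JAZ7, PIP1;5 and MYB47 stood at 0.496, 0.40, 0.346, 0.547 and 0.630. Without a size limit, 3247 genes were higher and 3001 lower with an interval that excluded no change, and the median log2 ratio over genes with at least 50 reads was 0.02.

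Among flowering-time regulators, FLC was the 1 member of 21 measured whose interval lay wholly above no change. The intervals of 6 members lay below no change and those of 14 included it. SNZ, an AP2-type floral repressor, stood at 0.609 of wild type (0.518 to 0.716), SOC1, a floral integrator repressed by FLC, at 0.635 (0.586 to 0.689), and MAF2, an FLC relative, at 0.708 (0.612 to 0.820). FT, the mobile flowering signal, had 5 reads in wild type and 9 in hlp1, too few to show a difference (ratio 1.3, 0.392 to 4.95). The median log2 ratio of the list was -0.03, at percentile 25.7 of 10000 random lists matched on expression, and turned to 0.036 with identical positions counted once. Of 10 autonomous-pathway and arginine methyltransferase genes, FCA, an RNA-binding repressor of FLC, was the 1 lower member, at 0.620 (0.530 to 0.726) with 350 and 300 reads, a log2 ratio of -0.69 that was -0.41 with positions counted once. FPA, another RNA-binding member of the pathway, was at 1.2 (1.05 to 1.48) and FVE at 1.14 (1.03 to 1.26). The list median was 0.08 (percentile 78.6). Of 23 cleavage and polyadenylation factors, 21 had intervals that included no change; the poly(A)-binding protein gene PABN3 was at 0.824 (0.746 to 0.910) and PCFS4 at 1.19 (1.04 to 1.36). Their list median was -0.02 (percentile 35.4), and 0.054 with positions counted once. The hnRNP A/B-like family, with 3 of 10 members above no change and 2 below, had a median of 0.08 (percentile 81.5).

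The heat shock list had the lowest median log2 ratio, -1.35 over 12 genes. Of these, 8 had intervals below no change, led by HSP22 with 39 reads in wild type and 6 in hlp1, while HSP101 was at 1.17 (1.02 to 1.34) and HSP70 at 1.01 (0.960 to 1.06). Of 9 jasmonate-responsive genes, 8 were lower, with a median of -0.77, which was -0.321 with identical positions counted once. JAZ10 and JAZ1, encoding repressors of the jasmonate response, stood at 0.479 (0.314 to 0.721) and 0.490 (0.389 to 0.615), and OPR3, an enzyme of jasmonate synthesis, at 0.559 (0.533 to 0.586). Of 13 cold- and abscisic acid-responsive genes, 8 were lower and COR15B was higher at 1.12 (1.02 to 1.23), with a median of -0.33, which was -0.166 with positions counted once. AT5G66400 (RAB18), a dehydrin gene, was at 0.580 (0.529 to 0.637), and P5CS1, of proline synthesis, at 0.630 (0.615 to 0.646). None of the 10000 random lists had a median as low as any of these 3 lists. Circadian clock genes had a median of -0.18 (percentile 1.18), with 3 of 13 lower: PRR7 at 0.648 (0.601 to 0.699), RVE8 at 0.759 (0.617 to 0.932) and LHY at 0.780 (0.622 to 0.979). Over all 16096 genes with at least 50 reads, 3001 were lower in this sense, a share not far from that of the clock list. SR splicing factors had a median of -0.14 (percentile 1.34; -0.084 with positions counted once), with 7 of 20 lower, such as SR30 at 0.737 (0.661 to 0.822) and RS31a at 0.785 (0.645 to 0.956).

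Other RNA-binding proteins had a median of 0.17 (percentile 99.5), with 10 of 17 higher, including RBP45C at 1.32 (1.24 to 1.42) and GRP7, a clock-regulated glycine-rich protein, at 1.27 (1.22 to 1.32). With identical read positions counted once, the medians of the RNA-binding and clock lists were 0.02 and -0.06, inside their random ranges. Salicylate defence genes had a median of -0.03 (percentile 34.2), which turned to 0.106 when counted so, with 2 of 8 lower, WRKY18 at 0.427 (0.366 to 0.496) and WRKY70 at 0.752 (0.568 to 0.997). Photosynthesis genes had a median of 0.01 (percentile 35.3), and 7 of 17 were higher and 6 lower. RBCS1B was at 0.731 (0.679 to 0.788) and RBCS1A at 1.23, both with intervals that excluded no change. Reads could be split among related members of this gene family, which was not tested. Root markers had a median of -0.10 (percentile 15.5), near 0 with identical positions counted once (-0.004), with 1 of 13 lower, COBL9 at 0.491 (0.259 to 0.911). Floral organ and seed markers had a median of 0.21 (percentile 86.1), with 2 of 6 higher and 1 lower, such as CRU3, a seed storage protein gene, at 1.35 (1.17 to 1.55) and SEP3 at 0.561 (0.372 to 0.843). Commonly used reference genes had a median of 0.17 (percentile 95.4), with 5 of 8 higher and 1 lower, from SAND at 0.775 (0.666 to 0.902) to EF1A at 1.40 (1.36 to 1.44). Their median was -0.13 with identical positions counted once. That count saturates in genes with many reads: photosynthesis, reference, jasmonate and cold or abscisic acid genes had medians of 76.3, 5.14, 4.69 and 3.75 wild-type reads per position, against 1.46 over all genes, so it gives no usable value for photosynthesis genes. Of the list genes named, HSP17.4, HSP101, JAZ10, AT5G66400, P5CS1, COR15B, FPA, FLD, RS31a, OLEO1 and EF1A have spans that overlap another gene.

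**Figure D2:**
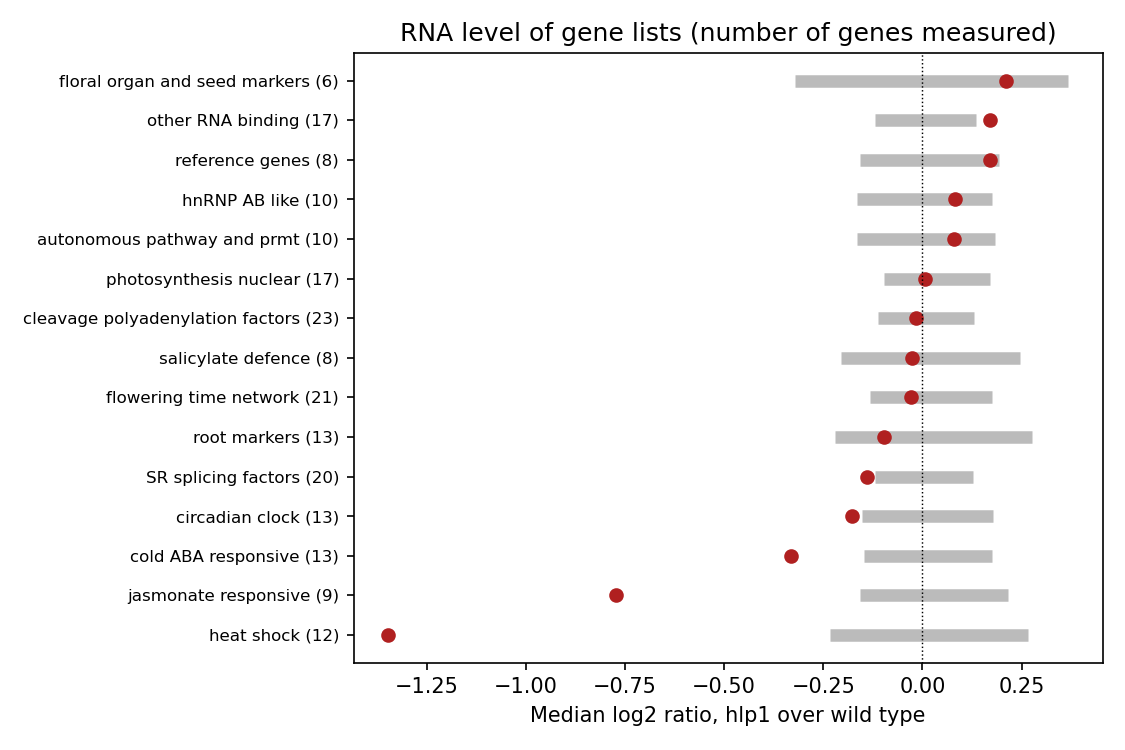
Median log2 ratio of hlp1 over wild type (x axis) for 15 gene lists (y axis, number of genes measured in brackets). Points are list medians, and grey bars span the central 95% of 10000 expression-matched random lists; heat shock (-1.35), jasmonate (-0.77) and cold or abscisic acid (-0.33) genes lie below their bars.

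CLIP tags were placed by strand and annotated gene. Of distinct HLP1 tags, 51.7% (51.7 to 51.8) lay in the sense strand of protein-coding genes, 14.4% (14.3 to 14.4) antisense to them and 23.0% (22.9 to 23.0) outside annotated genes. The RRM deletion gave 54.0% (53.6 to 54.4), 11.8% (11.6 to 12.1) and 21.6% (21.3 to 21.9). Of wild-type RNA-seq reads 97% were sense and 0.191% antisense, a contrast that is partly built in, since gene strands were inferred from the RNA-seq tracks. Genes for tRNA, rRNA, snoRNA and snRNA held 0.266% of HLP1 tags and 0.496% of deletion tags. In 8140 well-covered genes, stretches with RNA-seq depth under 10% of the gene mean, which are intron-like, made up 28.9% of the span and held 31.4% (31.3 to 31.5) of HLP1 tags and 29.5% (28.9 to 30.2) of deletion tags.

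HLP1 tags gathered towards and past the 3' ends of genes, the region where poly(A) sites lie. In 13231 genes, the last 150 nt held 9.54% of HLP1 tags and 1.84% of wild-type reads, a ratio of 5.17 (5.13 to 5.22, normal interval on the log scale). With windows of 100 and 300 nt the ratio was 11.3 (11.2 to 11.5) and 1.6 (1.59 to 1.61). The deletion library gave 9.67% and a ratio of 5.24 (5.04 to 5.46), so the measure did not separate the CLIP libraries. The mean profile of HLP1 peaked in the bin 175 to 150 nt before the annotated end, with 2.14% of the gene total per 25 nt, and that of wild-type RNA-seq 300 to 275 nt before it. RNA-seq coverage fell to 0.0507% in the last 25 nt, which raises the ratio. Beyond the annotated end, the next 200 nt held 12.4% of the gene's own tag total for HLP1, 10.4% for the deletion and 0.885% for wild-type RNA-seq; the 200 nt before the gene start held 5.14%, 3.75% and 1.04%. Neighbouring genes were not removed from these flanks.

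**Figure D3:**
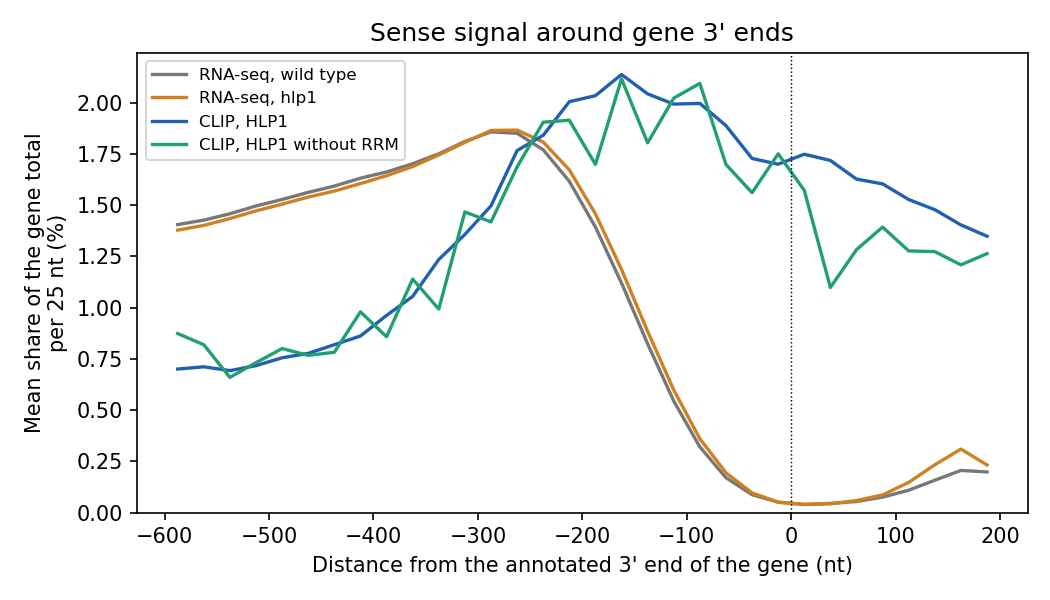
Mean share of each gene's sense signal per 25 nt (y axis) by distance from the annotated 3' end (x axis, negative inside the gene) for the 4 libraries, over 8142 genes (5553 with tags for the RRM deletion). Both CLIP profiles peak 175 to 150 nt before the end and continue past it, while RNA-seq coverage falls towards 0.0507% at the end.

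Tags per gene were set against wild-type RNA-seq reads, scaled so that the median gene has a ratio of 1. The tags came from 12-day-old seedlings carrying CFP-HLP1, while no age is given here for the wild-type RNA-seq plants. A high ratio could therefore also come from a difference between the plants, which was not tested. Transcripts rich in HLP1 tags included FCA (757 distinct tags, ratio 16.7, interval 14.7 to 19) and the FLC relatives MAF3 (502 tags, ratio 35.5, 28.8 to 44.0), FLM (639 tags, 10.5, 9.28 to 11.8) and MAF2 (384 tags, 7.84, 6.78 to 9.06). The much smaller RRM deletion library also had tags on FCA, MAF3, FLM and MAF2, at 33, 29, 27 and 17 distinct tags. Richness in HLP1 tags therefore does not show that binding depends on the RRM. FLC itself had 4 sense and 71 antisense HLP1 tags, and FT had 1 sense tag. SOC1 had 67 tags and a ratio of 0.40 (0.308 to 0.512). In all, 2932 of 12494 genes with at least 10 distinct tags were enriched, meaning an interval wholly above 2. With scaling to total tags and reads, 4878 genes were. Dividing by wild-type reads selects genes with few of them, so the median of 84 reads in enriched genes, against 428 in the other genes with 10 tags, follows from the definition. Across genes, which are not independent replicates, HLP1 tags and wild-type reads had a Spearman rho of 0.233.

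The most tags lay in RCD1, a regulator of stress responses, with 1457 distinct tags and a ratio of 5.08 (4.75 to 5.43). DMR6, a susceptibility gene for downy mildew, followed with 1323 tags (ratio 111, 89.6 to 138), then SOS3, a calcium sensor of salt tolerance, with 1109 (155, 118 to 207) and the transporter gene ABCC3 with 1070 (23.2, 20.6 to 26.2). BXL1, a beta-xylosidase gene, and TPS8, of the trehalose-phosphate synthase family, had 1068 and 957 tags at ratios of 0.814 (0.764 to 0.868) and 1.19 (1.11 to 1.27), and THA1, a threonine aldolase gene, had 861 tags (166, 121 to 234). Relative to RNA, the highest lower bounds belonged to genes with few reads, such as the transcription factor gene NAC074 (246 tags, 2 wild-type reads, ratio 947, 259 to 7863), the transporter gene ABCG38 (182 tags, 2 reads), the receptor-like protein gene RLP9 (722 tags, 30 reads), DREB19 (193 tags, 5 reads) and the floral homeotic gene PI (331 tags, 11 reads). PI also had 256 antisense tags. The spans of THA1 and DREB19 overlap another gene. The deepest single position, chromosome 2 at 6885711 (TAIR10, minus strand), had an HLP1 depth of 1041 and no RNA-seq reads and lay in the pseudogene AT2G15810. The next in an annotated protein-coding gene was chromosome 1 at 11613352 in RCD1, with a depth of 678.

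By list, SR splicing factors had the highest percentile of CLIP over RNA among random lists (99.97; median log2 1.32 relative to all genes), with 5 of 19 enriched, including SR34b at 6.09 (4.89 to 7.58) and RS31a at 4.85 (3.85 to 6.09). Cleavage and polyadenylation factors (percentile 99.5, median 1.3) had 5 of 23 enriched, among them PCFS5 at 27.1 (16.9 to 45.2) and PCFS1 at 18.1 (13.1 to 25.4). Clock genes (percentile 99.5, median 1.74) had 5 of 13 enriched, led by GI at 7.20 (6.18 to 8.39) and PRR3 at 7.11 (4.92 to 10.3). Of all genes with at least 10 tags, 2932 of 12494 were enriched. The SR and cleavage lists were close to that share, so their high percentiles rest on the medians, not on the counts of enriched genes. The autonomous-pathway list (percentile 84.2) had 4 of 10 enriched: FCA, FPA at 12.5 (10.5 to 14.9), FLD at 4.99 (3.82 to 6.5) and FLK at 2.92 (2.5 to 3.39). In the hnRNP A/B-like family (percentile 90.4), AT3G13224 and AT1G58470 were enriched at 5.79 (4.96 to 6.76) and 6.83 (4.51 to 10.3), and AT5G40490 was at 2.21 (1.82 to 2.65). The flowering-time list lay at percentile 87.5, other RNA-binding proteins at 92.8, salicylate defence at 82.4, reference genes at 86.0, root markers at 22.7 and heat shock genes at 16.6. Few tags for their RNA level fell on photosynthesis genes (median -6.95, none of 10000 random lists as low), cold- and abscisic acid-responsive genes (-4.07, percentile 0.02), the floral and seed markers OLEO1, CRU3, CRA1 and SEP3 (-2.76, or -1.43 with a pseudocount of 5, percentile 0.05) and jasmonate genes (-4.39, percentile 0.195). The floral gene PI, with 11 reads, was below the minimum of 20 for the median of its list and had a ratio of 232 (128 to 469). Photosynthesis genes had a median of 36251 wild-type reads, against 290 over all genes. The highest expression bin is open-ended, so their random lists (-4.34 to -1.88) also drew on less abundant genes. Since the ratio divides by reads, the low place of this list could come from abundance alone. Within the jasmonate list, LOX2, VSP1, VSP2, AOS, AOC1, OPR3 and LOX3 had ratios of 0.260 or less, while JAZ1 at 3.81 (2.95 to 4.90) and JAZ10 at 7.45 (5.14 to 10.8) were enriched.

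FCA was examined along its length, since alternative polyadenylation within it is known to set the amount of functional transcript. HLP1 tags formed a block of 2100 nt on the minus strand of chromosome 4, from 9211501 to 9213600 (TAIR10), which held 1537 tags, 82.9% of those in the gene, and reached a depth of 83. The gene spans used give no exons, so the block was not assigned to an intron. The deletion library had 28 of its FCA tags, 79.7%, in the same block. RNA-seq gave 42 wild-type and 43 hlp1 reads in the block and 160 and 134 reads on its 3' side. The odds of reads in the block over those on the 3' side were 1.22-fold higher in hlp1, with an exact conditional interval of 0.732 to 2.04 that included no difference. The 5' side was at 0.606 of wild type in hlp1 (0.474 to 0.775) and the 3' side at 0.606 (0.478 to 0.767).

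**Figure D4:**
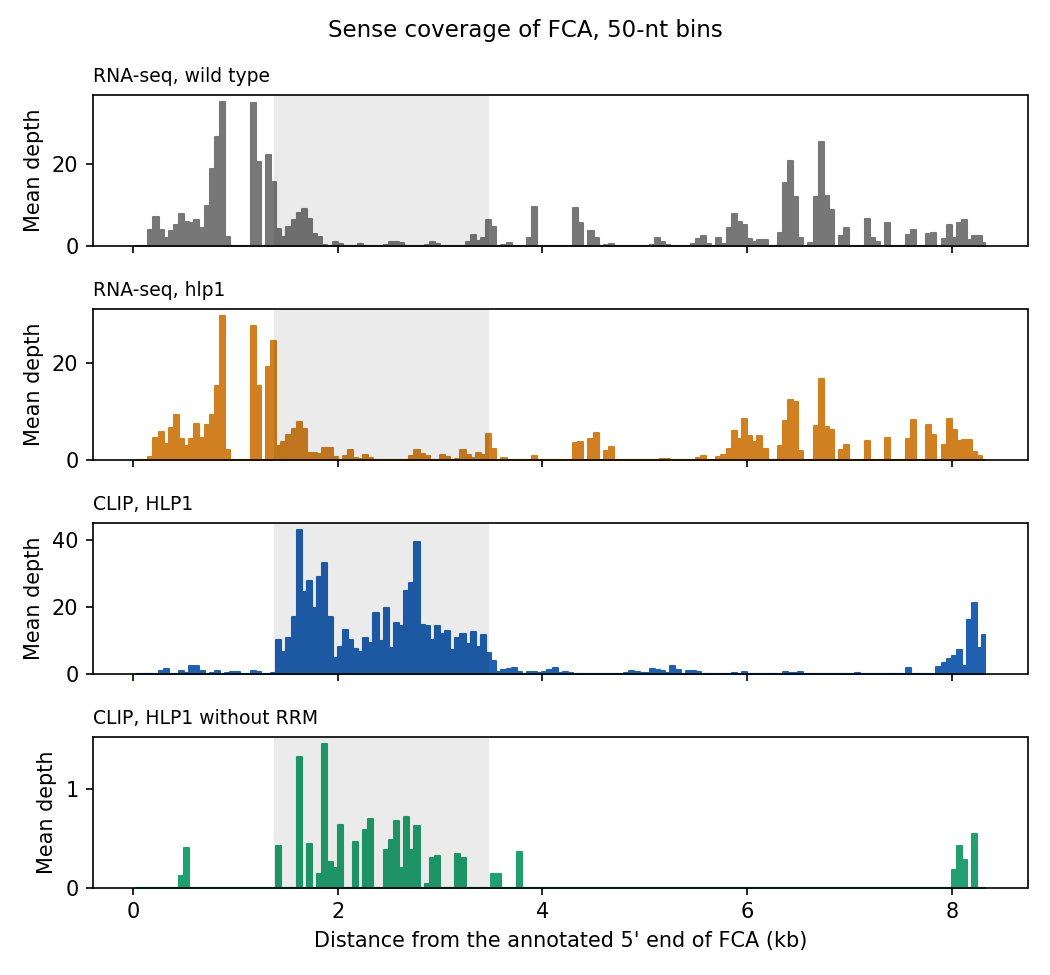
Sense coverage of FCA in 50-nt bins (y axis, mean depth, separate scales) by distance from the annotated 5' end (x axis, kb) in the 4 libraries. The grey band marks the 2100-nt block that holds 82.9% of HLP1 tags and 79.7% of deletion tags in the gene.

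The control without the RRM had a distribution of tags close to that of HLP1, at 37.7-fold fewer sense tags in genes. Of deletion coverage, 80.5% lay on bases also covered by HLP1 tags. Across 9742 genes the Spearman rho of the 2 libraries was 0.707, against 0.722 to 0.744 in 100 simulated subsamples of HLP1. Of 2073 genes with at least 5 expected or observed deletion tags, none had an interval of the HLP1 share wholly more than 2-fold above the deletion share. In 22 genes it lay wholly more than 2-fold below. Few deletion tags leave wide intervals on the upper side, as for NAC062, with 323 HLP1 tags and 1 deletion tag (share ratio 8.57, 1.53 to 340). The lack of calls above therefore does not show that no gene favoured HLP1. Genes below, named after their values were seen, included PRMT4B, an arginine methyltransferase gene with 31 HLP1 and 13 deletion tags. AT1G75770 was another, with 44 and 46 tags, the latter from 4 distinct starts, in a span that overlaps another gene. Tag numbers reflect library yield as well as binding and were not calibrated between the libraries.

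RNA levels of CLIP-enriched genes and their 3' ends were compared between wild type and hlp1. The 2746 enriched genes with at least 20 reads had a median log2 ratio of 0.0090, at percentile 2.1 of matched random lists (central 95% from 0.0095 to 0.0367). Of the enriched genes, AT1G75945 was higher and LOX4 and AT5G20790 were lower beyond 2-fold, named after their values were seen. The median was -0.004 and -0.006 under the other scalings, which shift the random lists alike. A gene chosen for few wild-type reads has a raised ratio of hlp1 to wild type by construction. As many genes as were enriched, those with the most tags, were therefore chosen without RNA after the data were seen. The 2906 of them with at least 20 reads had a median of -0.04, lower than in every random list. At gene ends, the share of reads in the last 200 nt of the terminal 400 nt was compared in 7994 genes, as a substitute for 3' UTR usage. No gene had more distal reads in hlp1 with an interval (Woolf) of the odds ratio wholly beyond 2-fold, and 2 had fewer: PIP1;5, with 18.4% distal in wild type and 0% of 124 reads in hlp1, which allows up to 2.41%, and HSD2, a CLIP-enriched hydroxysteroid dehydrogenase gene, with 12.7% and 2.0%. Neither gene kept this with identical positions counted once, when 0 genes had fewer distal reads, and 1 gene did in a 600-nt window and 1 with a later split. The median difference was 0.772 percentage points over all genes and 0.668 over 690 CLIP-enriched genes, at percentile 32.7 of matched lists; the latter was 0.231 (percentile 73.0) with positions counted once, 0.22 (percentile 86.7) with the later split and 0.529 (percentile 2.41), below the random range, in the 600-nt window. In simulated data, 69% of 4-fold rises in the odds were found by this measure, and 1 unchanged gene among 14416 was called. The simulation gave the window a larger part of each gene's reads and a larger distal share than these genes had on average. Falls in the odds were not simulated, so the 69% does not carry over to the genes measured.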

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

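All tests in this part except the comparison of RNA-seq antisense shares were chosen after the result was seen. The gene comparisons use sense tags, and the antisense strand was set aside. Of all distinct HLP1 tags, 14.4% lay antisense to protein-coding genes, more than the 11.8% of the RRM deletion, the control measured the same way; of the tags within these genes, 21.7% and 18.0% were antisense. Placement of short tags at random would leave long tags nearly free of antisense signal, but the antisense share of isolated 32-nt tags was 0.723 of that of 14 to 16-nt tags (28.3% and 39.2%). Scattered background would disappear from deep positions, yet bases at a depth of 8 or more still had 9.78% antisense coverage, down from 28.0% at a depth of 1, so both may contribute without being the whole cause. Antisense transcripts in the plants stay open. The RNA-seq antisense share was 1.62-fold higher in 2457 genes with at least 10 antisense HLP1 tags than in 10861 others (0.276% against 0.171%). That lies between the bounds set for and against them. These genes had at least 90% of RNA-seq coverage on 1 strand and spans without overlap. This leaves out genes with much antisense coverage and caps the share that could be measured. Counting identical starts once removes more tags from the deep sense strand of the larger library: with all tags, 18.8% of HLP1 and 17.5% of deletion tags within these genes were antisense, and the RRM as a source of the difference was not tested.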

How the results depend on the processing

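The alternatives of the CLIP-enriched gene comparison that change how genes are chosen, the 600-nt window, the order of gene classes and the per-gene mean were chosen after seeing the data. No paired analysis was possible because the groups with shared replicate numbers, the poly(A) site samples, were not analysed here, and the other groups have 1 library each. Counting identical read positions once gave 3 higher and 7 lower genes. XTH4 went from 2.27 to 1.03, but its 10516 hlp1 reads lay on 595 positions, a count that can saturate and does not test its ratio. HSP17.6A stood at 0.294 on fewer counts, with a wider interval (0.162 to 0.510). The cause was not tested for the other genes lost. This setting also moved the list medians of other RNA-binding proteins to 0.018, of the clock to -0.061 and of photosynthesis genes to -0.155, where a median of 76.3 reads shared each position, so that the count is saturated and says nothing about these genes. Both other scalings, reads on either strand and lower minimums kept all 6 higher and 26 lower genes; without overlapping genes 4 and 20 were left. HLP1 sense share was 52.4% with all tags and 50.9% with other genes given precedence, and the deletion share 53.1% in the latter case. Scaling to totals gave 4878 CLIP-enriched genes. The median RNA ratio of CLIP-enriched genes changed sign to -0.004 with trimmed mean scaling and -0.006 with median of ratios, where the random lists shift alike. It was -0.057 with genes chosen for few hlp1 reads, which lowers it by construction. With the genes of most tags it was -0.040, where the cause was not tested. Genes with fewer distal reads numbered 0 with positions counted once, 1 with a 600-nt window and 1 with a later split of the window; the distal difference of CLIP-enriched genes was 0.529 points with 600 nt, below its random range. FLC and FCA log2 ratios ranged from 1.35 to 1.74 and from -0.70 to -0.41, and gene-end ratios of HLP1 from 1.6 to 11.3, with intervals on the same side of no change in the alternatives run. Medians of jasmonate and cold or abscisic acid genes were -0.321 and -0.166 with positions counted once, still below their random ranges. UTR, intron, motif and isoform alternatives, and the choice of counting tags on either strand, were not run. Depth limits FT (5 and 9 reads) and most single genes of the deletion library.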

Other observations

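All tests in this part except those of shared starts and of the share of tags in enriched genes were chosen after the result was seen. RNA-seq coverage in the 200 nt past gene ends was 1.15% of the gene total in hlp1 and 0.885% in wild type, and in the 200 nt before genes 1.15% and 1.04%; neighbouring genes were not removed from these flanks. Among the listed genes with many antisense HLP1 tags were LD, an autonomous-pathway gene (233 antisense, 30 sense), RBP45A (160 and 54), SULTR1;2 (144 and 46) and PAB2 (118 and 74).

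The deletion library followed HLP1 gene by gene. In the test set beforehand, 42.9% of deletion starts coincided with an HLP1 start, with 82.0% of starts visible. Carry-over as the whole cause needed at least the 30.7% to 31.3% of simulated subsamples. The value met that 1-sided bound but lay above the whole simulated range, which no subsample reached. An HLP1 start also lay 1 nt to either side of 25.2% and 25.3% of deletion starts, and 5 nt away from 18.8% and 18.5%. The test therefore does not decide. A comparison chosen afterwards, the antisense share within protein-coding genes, went against carry-over as the whole cause by a small margin. It was 18.0% of distinct deletion tags (at most 18.4% by its interval). A subsample would lie between the 18.8% of all and 21.7% of distinct HLP1 tags. The interval covers counting error only, and deletion tags per gene varied more than that (Pearson chi-square per gene of 3.65 against a subsample). The margin therefore does not decide, and carry-over as the whole cause or as a part stays open. The Spearman rho of 0.707 lay below the lowest of 100 subsamples (0.722). The shares of 22 genes had intervals wholly beyond 2-fold, against at most 6 genes in subsamples. Neither value decides on carry-over, since duplicates of few tags, as in AT1G75770, could give both. Enriched genes held 41.4% of HLP1 and 43.2% of deletion sense tags, a ratio of 0.960, but carried-over tags would give equal shares whatever the RRM does, so dependence on the RRM also stays open, as do background common to both libraries and binding outside the RRM, which were not tested.

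Heat shock, jasmonate and cold or abscisic acid genes were lower in hlp1 together. Scaling or composition that acts as 1 factor on all genes is argued against as the whole cause. The median log2 ratio of all genes with at least 50 reads was 0.0175, against -0.33 for the highest of the 3 list medians. Library effects that differ between genes were not tested. Loss of direct binding stays open for all 3 lists. Of the jasmonate and cold or abscisic acid genes, 17 of 20 (85%) had fewer HLP1 tags for their RNA than the median gene, interval included. That count cannot decide it, since random lists matched on expression also lay below the median of all genes. Their log2 ranges were -3.19 to -0.11 for jasmonate and -2.76 to -0.17 for cold or abscisic acid. The list medians, -4.39 and -4.07, were lower still, while JAZ1 and JAZ10 were enriched. Of heat shock genes, 5 of 12 (41.7%) lay below the median gene and HSP23.6 was enriched. Harvest at another time of day may contribute: morning clock genes had a median log2 ratio of -0.34 and evening genes of 0.08, a difference of -0.42 that lies between the bounds set for and against it. Handling of the plants and the genotype itself cannot be told apart with 1 library each.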
